A study of Mus musculus with 6 samples.

How the data were processed

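Total RNA from whole inguinal mammary glands of 4-week-old C57BL/6J mice was hybridised to Affymetrix whole-transcript arrays from 400 ng of RNA per sample, per the labels' protocols. The labels name 6 biological replicates, 3 of wild type and 3 of a stromal knockout, and each gave 1 array. The deposited log2 values hold 1 signal per probe set and array, and the submitters' processing notes name RMA (background correction, quantile normalization and summary over probes) and limma, with no version. The base of the logarithm is not written in the value table and was taken as 2 from the use of RMA and from the range of the values. The chip definition, the probe filters and the level at which probes were summarised are not given in the sources used here. All 6 value columns were matched to samples by their labels.

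The table holds 41345 probe sets. The platform annotation lists 25335 of them, of which 23521 carry 1 gene symbol and 1814 several. The other 16010 probe sets are unnamed here. Symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which altered 0 symbols. That table also served to order neighbouring genes, and no coordinates are given because the value table names no assembly. Probe sets with 1 symbol were reduced to 22180 genes by keeping the probe set with the highest mean over the 6 arrays.

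Stromal knockout was compared with wild type by lmFit and eBayes of limma 3.58.1 in R 4.3.3, without an intensity trend, and p-values were adjusted over all genes by Benjamini-Hochberg with a threshold of 0.05. Standard errors are the moderated ones of that fit. Differences are knockout minus wild type on the log2 scale, and folds are the larger level over the smaller. The differences of Rnase2a, Cyp2b10, Krt14, Krt15, Fcer1a, Epb42, Tnni1 and Rps6ka6 and of probe set 17207079 can be read only as lower bounds. Each has a group mean under the 33rd percentile of gene levels (2.68). The knockout mean of Ttn lies under that level too, but its difference did not pass (limma adjusted p = 0.364) and is not read as a bound. Zic1 lay under that level in both groups. The number of arrays limits the precision. Mmp14 and Twist2 were also tested by an exact two-sided permutation test of 3 against 3 values, which cannot go below 0.1.

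Before the data were examined, 27 gene lists were fixed, among them markers of other cell types that the tissue could hold. Of 858 list entries, 789 matched a measured gene. Each list was set against all other genes by camera with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 27 lists. Camera was repeated with an estimated correlation, where it also tests on the fit's 4 residual degrees of freedom, far fewer than with the preset. Members past the threshold were counted over all genes and adjusted over the list alone.

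The rule for named genes was also fixed beforehand. It took Mmp14 and Twist2, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members past the threshold per list by size of change. For a list past the threshold with fewer than 2 such members, it took the 4 with the largest difference in the list's direction. Predicted genes, receptor segments and olfactory or vomeronasal receptors were left out of the rises and falls. Members that make up a count of 5 or fewer in a list were added after their values had been seen, unless the rule already named them. So were Ucp1, Zic1, Prdm16, Ppargc1a, Esr1, Elf5, Trp63, Col1a1, Fn1, Mmp2, Pdgfra, Adipoq, Lep, Fabp4, Krt1, Krt10 and the family members in the closing section.

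The alternatives were a filter on the lowest 33 percent of genes, an intensity trend, a robust trend, array weights, repeated quantile normalization, centring on array medians, the mean of a symbol's probe sets, every probe set tested, the replicate number as a block, an at least 2-fold change, an adjusted p under 0.1, and each array left out in turn. For gene lists, camera with an estimated correlation, fry, and a background of genes at or above the median level were added. Fry asks another question than camera, whether a list differs from no change rather than from all other genes, so its p is given beside the camera call and does not alter that call. The steps were tested on simulated data with the real genes' means and spread. In these, 30 genes were raised by 0.5 log2 units as a list, and 200 others of the 22180 genes were changed singly. For stromal knockout against wild type, 3 of 76 genes changed by 0.5 log2 units were recovered (3.95%), 33 of 57 changed by 1 unit (57.9%) and 61 of 67 changed by 2 units (91.0%). There were 4 false calls among 21950 unchanged genes, and 0 of 20 lists without a change passed camera. Noise was drawn for each gene on its own, so these lists held no correlation between members and do not test the preset correlation. A smaller share of genes was changed than was called in the data, so recovery there may differ.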

Results

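Gene expression was measured in whole inguinal mammary glands, which hold ductal epithelium, fat, fibroblasts, vessels and immune cells, taken from mice at 4 weeks of age, around the onset of puberty. One group of 3 mice carried both intact copies of Mt1-mmp, the gene now named Mmp14, which encodes a membrane-anchored matrix metalloproteinase. In the other group of 3 mice, a Cre recombinase expressed from the Dermo1 locus, now named Twist2 and active in mesenchymal cells, removed floxed Mt1-mmp from the stroma. The wild-type mice were littermates of the knockouts, per the series' design text. Array medians lay between 3.77 and 3.89 log2 units. Pearson correlations over the 22180 genes, which are not independent replicates, were 0.990 to 0.992 within a group and 0.975 to 0.983 between groups. The comparison asks what the loss of Mmp14 from stromal cells alters in the whole gland, and n = 3 arrays per group throughout. The labels name Dermo1-Cre only together with the floxed allele, so effects of Cre itself are not separated from the loss of Mmp14.

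Mmp14 itself, read by probe set 17300279, was 10.88 ± 0.32 (SD) in wild type and 8.62 ± 0.11 in the knockout. It fell by 2.25 ± 0.17 log2 units (SE), to 21.0% of the wild-type level (limma adjusted p = 0.000454). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give. All 3 knockout arrays lay under all 3 wild-type arrays, so the values go with the labels. Which part of the gene the probes read, relative to the deleted part, is not given in the sources used here. Twist2, read by probe set 17215799, was 4.33 ± 0.42 in wild type and 3.86 ± 0.33 in the knockout, a difference of -0.47 ± 0.24 that did not pass (limma adjusted p = 0.277, exact permutation p = 0.3).

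**Figure D1:**
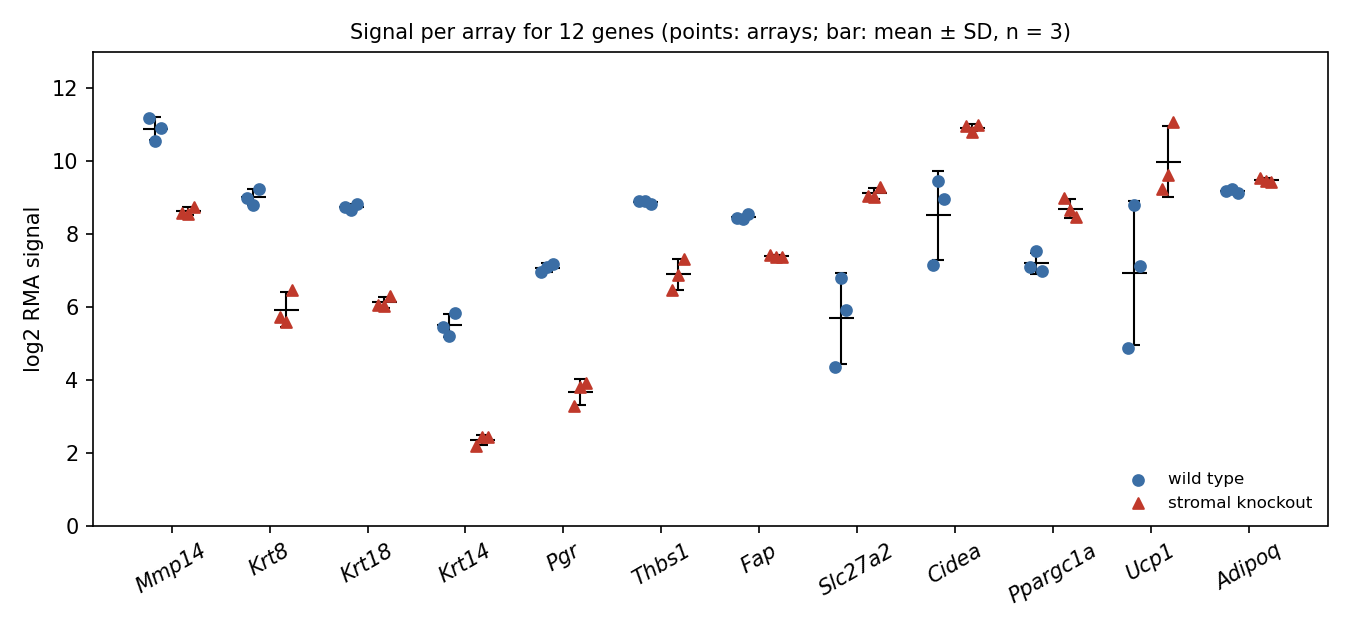
RMA signal on the log2 scale (vertical axis) of 12 genes (horizontal axis) on each array, with circles for wild type, triangles for the stromal knockout, and bars for mean ± SD over 3 arrays. Mmp14, Krt8, Krt18, Krt14, Pgr, Thbs1 and Fap lie lower on all 3 knockout arrays, Slc27a2, Cidea and Ppargc1a lie higher, and the wild-type values of Ucp1 spread from 4.88 to 8.80.

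The knockout differed from wild type in 2717 of 22180 genes (12.2%), of which 1121 rose and 1596 fell. At least 2-fold changes were seen in 190 genes that rose and 680 that fell. Rnase2a, an eosinophil-associated ribonuclease, had the largest rise as read, by 5.18 ± 0.21 log2 units (adjusted p = 6.03e-05), but its wild-type level of 2.30 lies under the 33rd percentile of gene levels (2.68), so the size can be read only as a lower bound. It was followed by Slc27a2, a fatty acid transporter and acyl-CoA synthetase (+3.43 ± 0.53, adjusted p = 0.00669), Cpne9 (+3.00 ± 0.49), Cidea, a lipid droplet protein of brown adipocytes (+2.40 ± 0.52), Anxa8 (+2.38 ± 0.54) and Pdk4, which inhibits pyruvate dehydrogenase (+2.36 ± 0.28). The remaining genes among the 10 largest rises were the mucin Muc2 (+2.22), the proton channel Otop1 (+2.12), Map7d2 (+2.03) and the cytochrome P450 Cyp2b10 (+2.01). The 10 largest falls began with Dmbt1, a scavenger receptor-like glycoprotein (-5.21 ± 0.35, 37.1-fold, adjusted p = 0.000287), Sprr1a, a cornified envelope precursor (-4.75 ± 0.73), and Cdcp3 (-4.71 ± 0.15). After these came the lysophospholipid transporter Mfsd2a (-4.02 ± 0.25), the tryptophan-degrading enzyme Ido1 (-3.91 ± 0.35), the chemokine Cxcl15 (-3.73 ± 0.20), Mtmr7 (-3.71 ± 0.15), Pcp4 (-3.51 ± 0.14), the retinol uptake receptor Stra6 (-3.47 ± 0.21) and the iodide transporter Slc5a5 (-3.47 ± 0.20). At least 1 knockout array of Dmbt1, Sprr1a, Cdcp3, Ido1 and Stra6 also read under 2.68. The same held for at least 1 wild-type array of Cpne9 and Map7d2, so the sizes of these changes may be lower bounds too. With each array centred on its median, which moved the median difference of all genes from 0.03 to 0.12, 1768 genes rose and 1333 fell. With 1 array fewer, 1490 genes passed without wild type 1 (521 rose, 969 fell), 2028 without wild type 2 (735 and 1293) and 1671 without wild type 3 (587 and 1084). Without knockout 1 the count was 1800 (695 and 1105), without knockout 2 it was 1497 (494 and 1003) and without knockout 3 it was 2304 (877 and 1427). Anxa8 lost its call without any 1 array other than knockout 3 (adjusted p 0.0505 to 0.102), Cidea without any knockout array (0.0579 to 0.0646), Otop1 without wild type 3 (0.0510) and Cyp2b10 without wild type 1 (0.0538).

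The lists for mammary epithelium lay lower in the knockout. Of 40 measured luminal genes, 33 fell and 0 rose, with 34 falls adjusted over the list alone. Pgr, the progesterone receptor, fell by 3.41 ± 0.18 log2 units (10.6-fold, adjusted p = 0.000154), and the keratins Krt19, Krt8 and Krt18 fell by 3.11 ± 0.26, 3.08 ± 0.24 and 2.62 ± 0.13. Elf5, a transcription factor of luminal progenitors, fell by 1.90 ± 0.17, whereas the oestrogen receptor gene Esr1, which stroma also expresses, differed by -0.11 ± 0.13 (adjusted p = 0.638). The luminal list had a median difference of -1.68 (camera adjusted p = 2.08e-31) and also passed with an estimated correlation (adjusted p = 0.0352), the only 1 of the 27 lists that did. Of 29 basal and myoepithelial genes, 18 fell and 0 rose, with 23 falls adjusted over the list alone. Krt14 fell by 3.15 ± 0.18 as read, a lower bound because its knockout level of 2.35 lies under the 33rd percentile of gene levels (2.68). Krt15 fell by 2.77 ± 0.41, the oxytocin receptor gene Oxtr by 2.43 ± 0.33 and the hemidesmosome collagen Col17a1 by 2.35 ± 0.16. Trp63, a transcription factor of basal cells, differed by -0.21 ± 0.21 (adjusted p = 0.584). The basal list had a median of -0.90 (camera adjusted p = 4.83e-16; adjusted p = 0.147 with an estimated correlation).

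**Figure D2:**
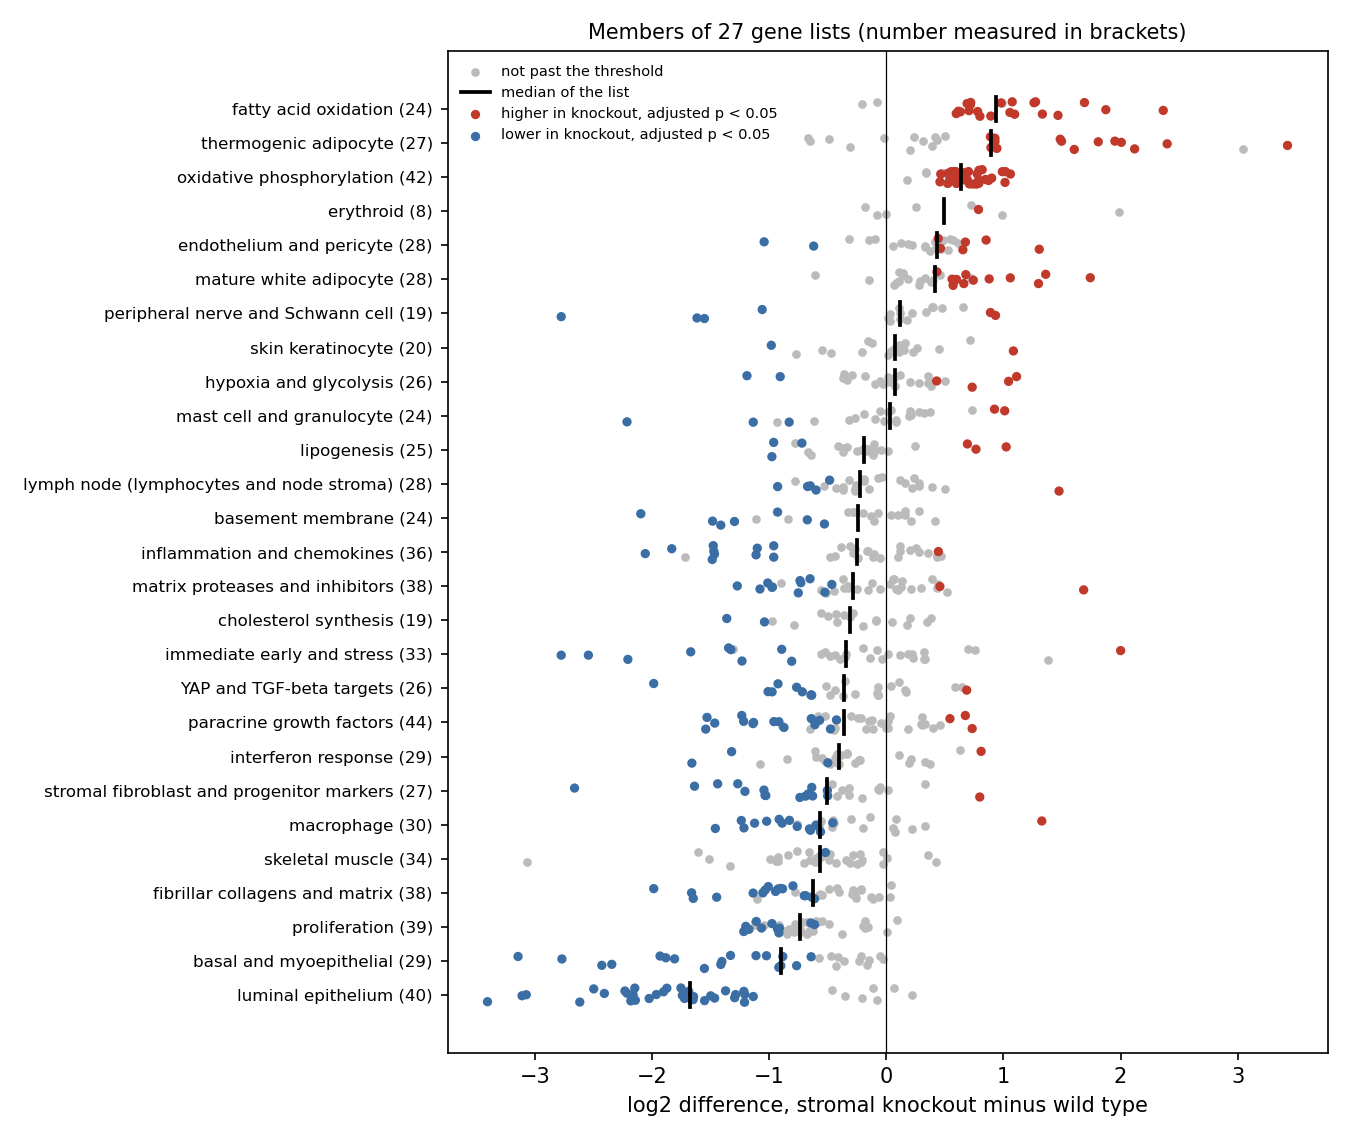
Log2 difference, stromal knockout minus wild type (horizontal axis), of each measured member of 27 gene lists (vertical axis, number measured in brackets). Red and blue points are members past the adjusted p threshold, grey points are not, and black bars are medians, which run from -1.68 for luminal epithelium to 0.94 for fatty acid oxidation.

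The matrix and fibroblast lists lay lower as well. Of 38 genes for fibrillar collagens and associated matrix, 17 fell and 0 rose, with 26 falls adjusted over the list alone. Thbs1, the matricellular protein thrombospondin 1, fell by 1.99 ± 0.20 log2 units (3.96-fold, adjusted p = 0.00133), tenascin C (Tnc) by 1.66 ± 0.28, Col12a1 by 1.65 ± 0.20 and fibronectin (Fn1) by 0.95 ± 0.13. Col1a1, a main chain of type I collagen, differed by -0.27 ± 0.16 (adjusted p = 0.344). The list median was -0.62 (camera adjusted p = 2.21e-14; adjusted p = 0.166 with an estimated correlation). Wild type 1, whose mean over 34 skeletal muscle genes lay 1.00 log2 units above the wild-type mean, was the highest array for this list and for the fibroblast, basement membrane and protease lists. Of 27 fibroblast and stromal progenitor markers, 15 fell (17 adjusted over the list alone), among them the hyaluronan synthase Has2 (-2.66 ± 0.17, 6.34-fold), Thy1 (-1.64 ± 0.13), Igfbp6 (-1.44 ± 0.17), Sfrp2 (-1.27 ± 0.15) and the receptor Pdgfra (-1.03 ± 0.13). Zfp423, a transcription factor of preadipocytes, was the 1 marker that rose (+0.80 ± 0.14, adjusted p = 0.0113; 1 adjusted over the list alone). The fibroblast list had a median of -0.50 (camera adjusted p = 7.01e-10; adjusted p = 0.147 with an estimated correlation). In the basement membrane list, 7 of 24 genes fell and 0 rose (9 and 1 adjusted over the list alone), led by the laminin chains Lama1 (-2.10 ± 0.25), Lama3 (-1.48 ± 0.15), Lamb3 (-1.41 ± 0.18) and Lama5 (-1.30 ± 0.20). Its median was -0.24 (camera adjusted p = 0.00128; adjusted p = 0.465 with an estimated correlation), and the call was lost against genes at or above the median level (0.0938), with a fry adjusted p of 0.107. The basement membrane median was -0.15 without wild type 1 and -0.13 without knockout 1. Lamb3 also stands in the basal and myoepithelial list, so its fall is counted in both.

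Proteases, growth factors and signalling targets moved in part. Of 38 other matrix proteases and inhibitors, 11 fell and 2 rose (14 and 2 adjusted over the list alone). The metalloproteinase Mmp16 fell by 1.27 ± 0.20 log2 units, the fibroblast protease Fap by 1.08 ± 0.11 and tissue plasminogen activator (Plat) by 1.01 ± 0.12. The metalloproteinase inhibitor Timp4 rose by 1.69 ± 0.13 (3.22-fold, adjusted p = 0.000476) and Adamts9 by 0.46 ± 0.11, a call lost without any 1 of the 6 arrays (adjusted p 0.0629 to 0.0920). Mmp2, whose proenzyme Mmp14 activates, differed by -0.55 ± 0.21 (adjusted p = 0.132), and by -0.77 without wild type 2 (adjusted p = 0.0340). The list had a median of -0.29 (camera adjusted p = 0.00388; adjusted p = 0.291 with an estimated correlation), and 6 members fell without wild type 1 and 7 without wild type 3 or any knockout array. Of 44 paracrine growth factors and their modulators, 15 fell and 3 rose (20 and 3 adjusted over the list alone). The falls were led by Fgf18 (-1.54 ± 0.19), Bmp7 (-1.53 ± 0.22), Inhbb (-1.47 ± 0.22) and Tgfb3 (-1.24 ± 0.16). The rises were Vegfa, an angiogenic factor (+0.73 ± 0.11), Btc (+0.67 ± 0.11) and Nrg4 (+0.54 ± 0.14), the last lost without wild type 1 or 3 or any knockout array (adjusted p 0.0939 to 0.141) and with repeated quantile normalization (0.0564). This list had a median of -0.36 (camera adjusted p = 0.000114; adjusted p = 0.166 with an estimated correlation), and 7 members fell without wild type 1 and 8 without wild type 2, knockout 1 or knockout 2. Among 26 YAP and TGF-beta targets, 7 of which stand in other lists, 8 fell and 1 rose (10 and 2 adjusted over the list alone), including Thbs1 and periostin (Postn, -0.93 ± 0.13). The rise of Tead1 (+0.69 ± 0.17) was lost without any 1 array other than knockout 3 (adjusted p 0.0950 to 0.113). The targets had a median of -0.36 (camera adjusted p = 0.00179; adjusted p = 0.364 with an estimated correlation), with 3 falls without wild type 1 or wild type 3 and 4 without wild type 2, knockout 1 or knockout 2, and a median of -0.23 without knockout 1.

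The lists for fatty acid oxidation, oxidative phosphorylation and thermogenic adipocytes lay higher in the knockout. Of 24 fatty acid oxidation genes, 21 rose and 0 fell (22 adjusted over the list alone), among them Pdk4 (+2.36 ± 0.28, 5.15-fold, adjusted p = 0.00245), the peroxisomal enzyme Ehhadh (+1.87 ± 0.14), the lipid-sensing receptor Ppara (+1.69 ± 0.26) and the thiolase Acaa2 (+1.47 ± 0.22). The list median was 0.94 (camera adjusted p = 1.65e-15; adjusted p = 0.166 with an estimated correlation). Of 42 genes for oxidative phosphorylation and the citric acid cycle, 35 rose and 0 fell (41 adjusted over the list alone), with Idh3a (+1.06 ± 0.15), Ndufb8 (+1.02 ± 0.15), Cyc1 (+1.01 ± 0.12) and Cox5a (+0.99 ± 0.18) in front. Their median was 0.64 (camera adjusted p = 1.39e-21; adjusted p = 0.166 with an estimated correlation), and 15 rose without knockout 2, 17 without wild type 1 and 22 without wild type 3. Of 27 thermogenic adipocyte genes, 14 rose and 0 fell (16 adjusted over the list alone). They included Slc27a2 (+3.43 ± 0.53, 10.7-fold), Cidea (+2.40 ± 0.52), Otop1 (+2.12 ± 0.41), the muscle-type cytochrome oxidase subunit Cox7a1 (+2.01 ± 0.36) and Ppargc1a, a coactivator of mitochondrial biogenesis (2.82-fold, adjusted p = 0.00312). Cidea lost its call without any knockout array (adjusted p 0.0579 to 0.0646) and Otop1 without wild type 3 (0.0510). Ucp1, the uncoupling protein of brown fat, was 6.93 ± 1.96 (SD) in wild type and 9.97 ± 0.97 in the knockout, a difference of +3.04 ± 0.91 (adjusted p = 0.0709), which passed with an intensity trend (adjusted p = 0.0286) and, at +3.97, without wild type 2 (adjusted p = 0.0277). Zic1, a marker of classical brown fat, was 1.93 in wild type and 1.91 in the knockout. Both values lie under the 33rd percentile of gene levels (2.68), where a change in it cannot be read. Prdm16, another member of the thermogenic list, differed by +0.42 ± 0.23 (adjusted p = 0.308), and knockout 1 lay under all 3 wild-type arrays. Without knockout 1, Prdm16 passed at +0.70 (adjusted p = 0.0269). The thermogenic median was 0.89 (camera adjusted p = 1.76e-07; adjusted p = 0.166 with an estimated correlation). Wild type 1, the array with the highest muscle mean, was the lowest array for all 3 of these lists, at -0.31 from the wild-type mean for thermogenic genes, -0.15 for fatty acid oxidation and -0.15 for oxidative phosphorylation.

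**Figure D3:**
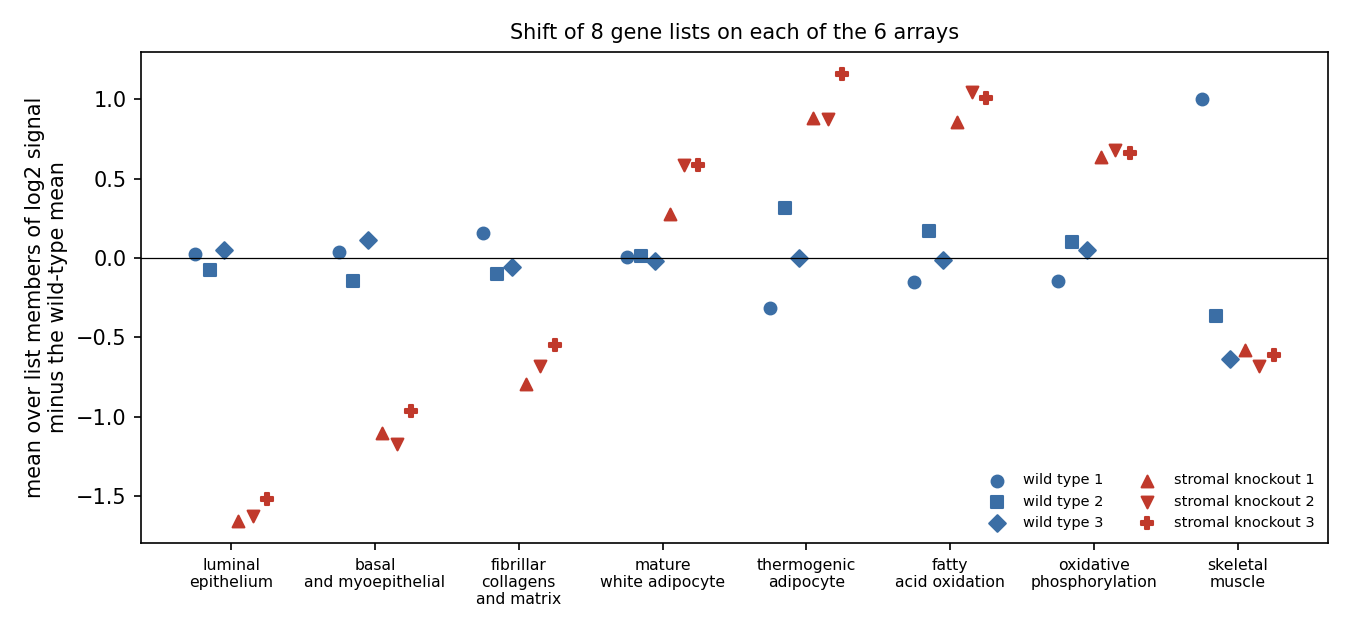
Mean over list members of the log2 signal minus the wild-type mean (vertical axis) for 8 gene lists (horizontal axis) on each of the 6 arrays, blue for wild type and red for the stromal knockout. The 3 knockout arrays lie apart from the 3 wild-type arrays in the first 7 lists, while the skeletal muscle list stands at 1.00 on wild type 1 and between -0.68 and -0.37 on the other arrays.

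Of 28 mature white adipocyte genes, 12 rose and 0 fell (17 adjusted over the list alone), among them the imprinted gene Nnat (+1.74 ± 0.23), the glycerol channel Aqp7 (+1.36 ± 0.13), Pck1, an enzyme of glyceroneogenesis (+1.30 ± 0.24), and the activin-type receptor gene Acvr1c (+1.06 ± 0.16). The adipokine genes Adipoq and Lep differed by +0.29 ± 0.11 (adjusted p = 0.133) and -0.15 ± 0.20 (adjusted p = 0.698), and Fabp4 by +0.11 ± 0.11 (adjusted p = 0.577). Fabp4 lay at 12.73 in wild type and 12.84 in the knockout, near the array maxima of 13.3 to 13.4, so a rise may be understated. Adipoq passed with an intensity trend (adjusted p = 0.0322) and with a robust trend (0.0348). The list median was 0.41 (camera adjusted p = 1.01e-07; adjusted p = 0.166 with an estimated correlation), and 4 members rose without knockout 2, 6 without wild type 2 or wild type 3 and 7 without knockout 3. Of 25 lipogenesis genes, Acacb (+1.02 ± 0.13), Lpin1 (+0.77 ± 0.12) and Dgat1 (+0.69 ± 0.11) rose, and Pnpla3 (-0.98 ± 0.23), Mid1ip1 (-0.96 ± 0.19) and Fads2 (-0.72 ± 0.15) fell, with 3 rises and 5 falls adjusted over the list alone. Acacb makes the malonyl-CoA that restrains fatty acid oxidation, and Lpin1 and Dgat1 act in triglyceride assembly. The list median was -0.19 (camera adjusted p = 0.0408; adjusted p = 0.489 with an estimated correlation), and the list lost its call without wild type 1 (adjusted p = 0.174), knockout 1 (0.180) or knockout 2 (0.0854), with low genes left out (0.136), with the mean of probe sets (0.0590) and against genes at or above the median level (0.113), and fry gave 0.350. The lipogenesis median was -0.11 without knockout 1 and -0.36 without knockout 3. Without knockout 3, 7 members fell. Pnpla3 lost its call without any wild-type array or knockout 2 (adjusted p 0.0507 to 0.108), Fads2 without wild type 1, wild type 3, knockout 1 or knockout 2 (0.0646 to 0.0789), and Mid1ip1 without wild type 2 (0.0538) or knockout 1 (0.0550). The mean of its probe sets put Mid1ip1 at -0.24 (adjusted p = 0.296). Of 19 cholesterol synthesis genes, squalene epoxidase (Sqle, -1.36 ± 0.12, 2.57-fold) and Sc5d (-1.04 ± 0.15) fell and 0 rose, with 7 falls adjusted over the list alone. The median was -0.31 (camera adjusted p = 0.00179; adjusted p = 0.293 with an estimated correlation), and 5 members fell with low genes left out and 6 with either trend.

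The proliferation, macrophage, inflammation and immediate early lists had negative medians. Of 39 proliferation genes, 11 fell and 0 rose (30 adjusted over the list alone). The replication helicase genes Mcm5 and Mcm6 fell by 1.22 ± 0.17 and 1.11 ± 0.13 log2 units. Mki67 fell by 1.20 ± 0.27, a call lost without wild type 1, wild type 2, knockout 1 or knockout 2 (adjusted p 0.0549 to 0.0922). The list median was -0.74 (camera adjusted p = 1.38e-12; adjusted p = 0.273 with an estimated correlation), and 2 members fell without wild type 1, 4 without knockout 1, 5 without wild type 2 and 18 with either trend. Of 30 macrophage genes, 14 fell and 1 rose (20 and 1 adjusted over the list alone). The Fc receptor gene Fcgr1 fell by 1.46 ± 0.20, the chemokine receptor gene Cx3cr1 by 1.24 ± 0.13 and the lysosomal marker Cd68 by 1.22 ± 0.14, while the glycoprotein gene Gpnmb rose by 1.33 ± 0.24. The macrophage median was -0.57 (camera adjusted p = 3.66e-08; adjusted p = 0.166 with an estimated correlation), with 6 falls without wild type 1, 7 without knockout 2, and 8 without wild type 3 or knockout 1. Of 36 inflammation genes, 10 fell and 1 rose (11 and 2 adjusted over the list alone), and the chemokine genes Ccl3, Cxcl14, Ccl8 and Cxcl16 fell by 2.06 ± 0.21, 1.83 ± 0.19, 1.49 ± 0.26 and 1.48 ± 0.19. The rise of Nfkbia, an inhibitor of NF-kappa-B (+0.44 ± 0.12), was lost without any 1 of the 6 arrays (adjusted p 0.0866 to 0.133), with array weights (0.0522) and with repeated quantile normalization (0.0639). The inflammation median was -0.25 (camera adjusted p = 0.00179; adjusted p = 0.166 with an estimated correlation). Of 33 immediate early and stress genes, 9 fell and 1 rose (9 and 3 adjusted over the list alone), with the transcription factors Egr2 and Egr3 at -2.78 ± 0.25 and -2.55 ± 0.27 and the chaperone gene Hspa1b at -2.21 ± 0.20. Nr4a3, a nuclear receptor, rose by 2.00 ± 0.49, a call lost without any 1 array other than knockout 3 (adjusted p 0.0508 to 0.110), while 4 of these genes rose without knockout 3. Their median was -0.35 (camera adjusted p = 0.00272; adjusted p = 0.232 with an estimated correlation), and it was -0.22 without wild type 3 and -0.10 without knockout 1.

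Other immune lists held few changed members. Of 29 interferon response genes, Ifit1 (-1.66 ± 0.39), Oas2 (-1.32 ± 0.25) and Stat2 (-0.50 ± 0.13) fell and Ifi27 rose (+0.81 ± 0.12, adjusted p = 0.00565), with the same counts, 3 and 1, adjusted over the list alone. Ifit1 lost its call without any wild-type array or knockout 2 (adjusted p at least 0.0593), Oas2 without wild type 3 (0.0548), and Stat2 without any 1 array other than wild type 2 (0.0762 to 0.135) and with arrays centred (0.0729). The list median was -0.40 (camera adjusted p = 0.00553; adjusted p = 0.470 with an estimated correlation), with the call lost without wild type 3 (adjusted p = 0.0599), with low genes left out (0.0542) and against genes at or above the median level (0.113), and fry gave 0.248. Without knockout 1 the median was -0.25. Interferon genes that fell numbered 0 without wild type 3, 1 without knockout 2 and 5 without knockout 3. Of 28 lymph node genes, the pan-leukocyte gene Ptprc (-0.93 ± 0.14, adjusted p = 0.00576), Ighm (-0.67 ± 0.17), Coro1a (-0.65 ± 0.14), Cd79b (-0.60 ± 0.12) and Cd2 (-0.48 ± 0.13) fell and the B cell chemokine gene Cxcl13 rose (+1.47 ± 0.37), again with 5 and 1 adjusted over the list alone. Ighm lost its call without any 1 array other than wild type 2 (adjusted p 0.0796 to 0.129), Coro1a without wild type 1, wild type 3, knockout 2 or knockout 3 (0.0656 to 0.0855), and Cd79b without wild type 1, wild type 3, knockout 1 or knockout 2 (0.0559 to 0.0676). Cd2 lost it without any 1 array other than wild type 1 (0.0973 to 0.137), with either trend, with centred arrays and with repeated quantile normalization (0.0715 to 0.124), and Cxcl13 without any 1 other than knockout 3 (0.0934 to 0.119). The mean of its probe sets put Ighm at -0.08 (adjusted p = 0.766), and centred arrays gave it an adjusted p of 0.0566. Lymph node genes that fell numbered 2 without wild type 1 or knockout 1, 1 without wild type 3 or knockout 2, and 3 without knockout 3. The lymph node median was -0.22 (camera adjusted p = 0.0365; adjusted p = 0.381 with an estimated correlation), and the call was lost without wild type 2 (0.106), wild type 3 (0.0990), knockout 1 (0.0879) or knockout 2 (0.0568) and in 5 other settings (0.0545 to 0.0938), and fry gave 0.105. Of 24 mast cell and granulocyte genes, Hdc (+1.01 ± 0.25) and Fcer1a (+0.92 ± 0.17) rose, and Ltf (-2.22 ± 0.13), Kit (-1.14 ± 0.15) and Prtn3 (-0.83 ± 0.18) fell, with 3 rises and 5 falls adjusted over the list alone. Ltf and Kit also stand in the luminal list. Hdc lost its call without any 1 array other than knockout 3 (adjusted p 0.0663 to 0.117) and Prtn3 without any 1 other than knockout 1 (0.0586 to 0.0751). This list did not pass (camera adjusted p = 0.562), and its median of 0.03 and mean of -0.09 differ in sign. The median was -0.05 without wild type 2 and -0.02 without knockout 1.

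Vessel, nerve, skin, muscle, red cell and hypoxia genes were read as markers of other parts of the tissue. Of 28 endothelial and pericyte genes, 6 rose and 2 fell (12 and 3 adjusted over the list alone), led by the tight junction gene Cldn5 (+1.31 ± 0.23) and the VEGF receptor gene Kdr (+0.85 ± 0.12). The 2 that fell were Reln (-1.04 ± 0.14) and Pdpn (-0.62 ± 0.13), Pdpn with a call lost without any 1 array other than knockout 1 (adjusted p 0.0546 to 0.0835). The endothelial median was 0.43 (camera adjusted p = 0.000314; adjusted p = 0.421 with an estimated correlation; fry adjusted p = 0.0700), with 2 rises without knockout 2, 3 without wild type 1, wild type 2 or knockout 3, 10 with either trend and 11 with centred arrays. Of 19 nerve genes, Egr2 (-2.78 ± 0.25), Erbb3 (-1.62 ± 0.17), Sox10 (-1.55 ± 0.18) and Ngfr (-1.06 ± 0.20) fell and Fa2h (+0.93 ± 0.13) and S100b (+0.89 ± 0.17) rose (4 and 5 adjusted over the list alone), with Ngfr and S100b losing their calls without wild type 1 (adjusted p 0.0514 and 0.0638). The nerve list did not pass (camera adjusted p = 0.562, median 0.12, mean -0.11), and 15 of its members were higher and 4 lower. Egr2, Sox10 and S100b also stand in the immediate early, basal and thermogenic lists. Of 20 skin keratinocyte genes, Cdsn rose (+1.09 ± 0.22) and Tgm3 fell (-0.98 ± 0.19), with 1 and 1 adjusted over the list alone. Cdsn lost its call without wild type 2, wild type 3, knockout 2 or knockout 3 (0.0507 to 0.0699) and Tgm3 without wild type 2, knockout 1 or knockout 2 (adjusted p up to 0.0559). The skin median was 0.07 (camera adjusted p = 0.969), and the epidermal keratins Krt1 and Krt10 differed by +0.26 ± 0.26 and +0.11 ± 0.15. Of 34 skeletal muscle genes, Tnni1 fell (-0.52 ± 0.13), a call lost without any 1 array other than wild type 3 (0.0765 to 0.113) and with either trend or centred arrays (0.0667 to 0.0888), and 0 passed adjusted over the list alone. The largest muscle differences were those of Myh4 (-3.07 ± 0.91, adjusted p = 0.0683), Actn3 (-1.61 ± 0.61), Atp2a1 (-1.52 ± 0.93) and Ttn (-1.34 ± 0.84), and Myh4 passed with an intensity trend (adjusted p = 0.0289) and without wild type 3 (0.0271). The muscle median was -0.57 (camera adjusted p = 0.000314; adjusted p = 0.474 with an estimated correlation), and without wild type 1 it was -0.11 (camera adjusted p = 0.193). The muscle call was also lost against genes at or above the median level (0.711), and fry gave 0.274. Of 8 erythroid genes, Epb42 rose (+0.78 ± 0.17), a call lost without any wild-type array (0.0543 to 0.0757), with 4 rises adjusted over the list alone. The erythroid median was 0.49 (camera adjusted p = 0.0749), and the list passed without wild type 2 (0.0482), knockout 1 (0.0190) or knockout 3 (0.0480), with low genes left out (0.0153, on 5 members) and with array weights (0.0412). Rises numbered 3 without knockout 1 or with an intensity trend, and 2 with a robust trend or centred arrays. Of 26 hypoxia and glycolysis genes, Ddit4 (+1.11 ± 0.20), Bnip3 (+1.04 ± 0.18), Vegfa (+0.73 ± 0.11) and Pgk1 (+0.43 ± 0.11) rose, while P4ha2 (-1.19 ± 0.18) and P4ha1 (-0.91 ± 0.15), which hydroxylate collagen, fell (8 and 3 adjusted over the list alone). Pgk1 lost its call without any 1 of the 6 arrays (adjusted p 0.0715 to 0.141), with array weights (0.0540) and with repeated quantile normalization (0.0762), and the list did not pass (median 0.07, camera adjusted p = 0.230), while fry, which tests against no change, gave 0.0291. With either trend or centred arrays, 8 hypoxia genes rose.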

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

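The tests of epithelial share, skin, adipocyte share, wild type 1 and the neighbourhood of Mmp14 were chosen only after the results they bear on had been seen. Among probe sets that the annotation table does not list, 98 were higher and 142 lower in the knockout when every probe set was tested by limma, and among those with several gene symbols 23 were higher and 33 lower. None of these entered the gene comparison. Examples of unlisted probe sets are 17243761 (+4.55 ± 0.38 log2 units) and 17307446 (+4.29 ± 0.26), which were higher, and 17439029 (-3.83 ± 0.61) and 17207079, which were lower. The last was read at -4.47, a lower bound in size because its knockout level of 2.47 lies under the 33rd percentile of gene levels (2.68). Only 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave 2717 genes past the threshold, and the highest other split gave 0. For gene lists, again 1 of 10 splits gave 22 lists with the preset correlation, and the highest other split gave 16. Every other split mixes the genotypes unevenly, so its groups still hold part of the genotype difference, while the rest widens the spread within groups. Neither the 0 genes nor the 16 lists is therefore a rate expected without a genotype difference. With 10 splits a share under 0.05 cannot be reached.

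Of 57 luminal and basal markers with a wild-type level above the median gene, 48 (84.2%) fell and none rose, but these markers make up the pattern itself, so the count gives no support to a smaller epithelial share over lower expression per cell. More skin in the wild-type tissue is argued against, since the skin list had a median of 0.0744 and Krt1 and Krt10 did not fall past the threshold. The genes Esr1 and Trp63 did not pass, at -0.11 ± 0.13 and -0.21 ± 0.21. Whether the pattern may come from less duct growth, from less epithelium in the part of the gland taken, or from lower expression per epithelial cell stays open, because tissue was read whole and no array separates these.

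The thermogenic list mean was higher in all 3 knockout arrays than in any wild-type array, and a larger adipocyte share alone could give that if white adipocyte genes shifted as much. Over all members, the 27 thermogenic genes shifted by 0.973 log2 units and the 28 white adipocyte genes by 0.483, a difference of 0.490 whose 95% interval, -0.0799 to 1.06, includes 0. To leave out saturated signals, a selection made after the data were seen kept members with mean levels from 5 to 11. Over these 18 and 20 members the difference was 0.811 (95% interval 0.0123 to 1.61, and 0.576 without wild type 1), so a larger adipocyte share is not excluded. Wild type 1 alone is argued against, since 12 thermogenic members rose without it (camera adjusted p = 4.03e-08). A more thermogenic adipocyte state after stromal loss of Mmp14 and a larger adipocyte share both stay open. So do untested differences between the mice, such as the Dermo1-Cre allele, body weight or the part of the gland taken.

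Rnase2a, the largest rise as read, lies near Mmp14 in the gene order of GRCm38.p6, with 45 measured genes between them, so DNA from the strain in which the floxed allele was made may have been carried along. Of the 200 measured genes nearest to Mmp14, 22 passed (15 rose, 7 fell), against a median of 24 over 17984 runs of the same size, and 69.3% of runs held at least as many. Near Twist2, where DNA carried along with the Dermo1-Cre allele could act in the same way, 22 of 200 also passed (7 rose, 15 fell). A count at or below the median, the bound set beforehand for Twist2 and only after the result was seen for Mmp14, was met in both regions but by less than the spread between runs, and the rule that this leaves the matter open was set after the counts were seen. Carried-along DNA and loss of Mmp14 cannot be told apart for single genes such as Rnase2a, because every knockout mouse carries both alleles. Effects of the Dermo1-Cre allele itself are likewise tied to loss of Mmp14 for every gene and list, since no label names that allele alone.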

How the results depend on the processing

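Mmp14 kept its direction and its call under every alternative that was run on it, at -2.42 to -2.10. Of 2717 genes (1121 higher, 1596 lower), leaving out 1 array gave 1490 to 2304 in total, 494 to 877 higher and 969 to 1427 lower, and such fits have fewer samples. With the replicate block, 1923 genes passed (689 higher, 1234 lower), of which 1817 were shared with the fit without it. Deviations of same-numbered arrays correlated at -0.0343, -0.0524 and -0.0320, so no array was closest to its own number. With 3 arrays per group these values cannot exclude that the mice were paired, and the sample labels name no litter. Centring arrays on their medians gave 1768 higher and 1333 lower. An at least 2-fold change gave 870 (190 higher, 680 lower), an adjusted p under 0.1 gave 4090 (1857 higher, 2233 lower), and testing every probe set, with more tests to adjust for, gave 1647 (568 higher, 1079 lower). The filter on low genes, both trends, array weights, repeated quantile normalization and the mean of probe sets gave 2645 to 3462 genes.

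Of the 22 lists that passed, 1 passed with an estimated correlation. Those with at least 10 changed members, a selection made after the data were seen, then had adjusted p = 0.147 (fibroblast, basal), 0.166 (fibrillar matrix, white adipocyte, thermogenic, fatty acid oxidation, oxidative phosphorylation, growth factors, macrophage, inflammation), 0.232 (immediate early), 0.273 (proliferation) and 0.291 (proteases). This p takes the correlation between members from the 6 arrays and tests on 4 residual degrees of freedom. A lost call therefore does not reflect correlation alone. For inflammation, with an estimated correlation of 0.022, the camera adjusted p went from 0.00179 to 0.166. For hypoxia, with an estimate of -0.003, it went from 0.230 to 0.364. Fry, which tests each list against no change and not against other genes, passed 17 lists, hypoxia among them but not basement membrane, lipogenesis, lymph node, muscle, endothelium or interferon. The background of genes at or above the median level passed 17, without basement membrane, lipogenesis, lymph node, muscle and interferon, while the other alternatives passed 20 to 23, and no list or named gene that passed turned its direction. Of the 116 genes named by rule besides Mmp14, 2 lost their call with centred arrays, 2 with the mean of probe sets and 8 with the replicate block, and 6 to 18 lost it when 1 array was left out. Calls were gained by Myh4 (trend, replicate block 0.0284, without wild type 3) and Ucp1 (trend, replicate block 0.0415, without wild type 2). Adipoq gained its call with both trends, Mmp2 without wild type 2 and Prdm16 without knockout 1. The erythroid list also passed with the replicate block (0.0333). The cause of these changes was not tested. Genes with levels near the bottom of the scale, such as Krt14 in the knockout, have little signal over background, which limits how low they can be read.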

Other observations

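The grouping of genes into families by the letters of their symbols was chosen after other results had been seen, whereas the prediction that at least 1 family passes was set before that test was run. Of 248 families with at least 10 measured genes, 24 passed camera with the preset correlation and 0 with an estimated correlation. Subunits of the mitochondrial ribosome were among them, with 15 of 43 Mrpl genes and 8 of 28 Mrps genes higher and 0 lower, at medians of 0.44 and 0.33 log2 units (camera adjusted p = 2.26e-08 and 3.26e-06; adjusted p = 0.375 and 0.444 with an estimated correlation). Peroxisome biogenesis genes (Pex) rose in 7 of 14 cases, with Pex16 at +0.81 ± 0.14, and coenzyme Q synthesis genes (Coq) in 5 of 11, with Coq8a at +1.74 ± 0.21 (3.34-fold, limma adjusted p = 0.00256). The other Coq genes that rose were Coq9 (+0.76 ± 0.13), Coq3 (+0.83 ± 0.17), Coq6 (+0.61 ± 0.13) and Coq8b (+0.63 ± 0.16). Coq3 lost its call without wild type 1, wild type 2, knockout 2 or knockout 3 (adjusted p 0.0510 to 0.0614), Coq6 without wild type 3 or knockout 2 (0.0669 and 0.0718) and Coq8b without any 1 array other than knockout 3 (0.0679 to 0.114). The medians of Pex and Coq were 0.53 and 0.52 (camera adjusted p = 8.76e-05 and 0.000148; adjusted p = 0.596 and 0.695 with an estimated correlation). Of 45 Rpl and 41 Rps genes, which encode mainly the cytosolic ribosome, 0 Rpl genes passed by limma, while the kinase gene Rps6ka5 (+0.65 ± 0.15) rose and the kinase gene Rps6ka6 fell, by 1.06 as read, a lower bound because its knockout level of 2.51 lies under the 33rd percentile of gene levels (2.68). Neither of these encodes a ribosomal protein, and both lost their call without wild type 1 or any knockout array, Rps6ka5 also without wild type 3 and Rps6ka6 without wild type 2 (adjusted p 0.0604 to 0.105).

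Part of the integrin genes fell. Of 12 genes with the symbol stem Itgb, 6 fell and 0 rose, among them the beta chain genes Itgb3 (-1.44 ± 0.24) and Itgb8 (-1.14 ± 0.15). The stem alone set this family, so its members need not all be beta chains. Of 11 alpha chain genes (Itga), 4 fell, namely Itga2 (-1.30 ± 0.13), Itga8 (-1.14 ± 0.11), Itga4 (-0.94 ± 0.13) and Itga3 (-0.76 ± 0.18). Itga7 rose (+1.09 ± 0.15). Itga3 lost its call without wild type 1, wild type 3, knockout 1 or knockout 2 (adjusted p 0.0748 to 0.103). The medians were -0.53 and -0.60 (camera adjusted p = 0.0265 and 0.00288; adjusted p = 0.777 for both with an estimated correlation). Of 20 tumour necrosis factor receptor family genes (Tnfrsf), 6 fell and 0 rose, with Tnfrsf12a at -1.39 ± 0.17 and Tnfrsf18 at -1.38 ± 0.15, and the median was -0.40 (camera adjusted p = 0.00122; adjusted p = 0.596 with an estimated correlation). The medians of these families kept their sign with repeated quantile normalization and with centred arrays.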
